A study of Homo sapiens with 12 samples.

How the data were processed

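Expression was measured on 12 oligonucleotide arrays with 22283 probe sets each, hybridised with biotin-labelled material from total RNA of the breast cancer cell line MCF-7. Per the labels, the cells carried an adenovirus with an estrogen receptor beta insert (AdERb) at 5 or 50 infectious units per cell (the multiplicity of infection, moi), or an adenovirus without insert (Ad) at moi 50, and 48 h later were given vehicle or 10 nM estradiol (E2) for 24 h. These conditions gave 6 groups of 2 arrays. No group carried the virus without insert at moi 5, so AdERb at moi 5 and Ad differ in total virus dose as well as in the insert.

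The authors deposited one intensity per probe set and array, made with GCRMA per the submitters' processing notes, which give no version. GCRMA corrects for background, normalises between arrays by quantiles and summarises probes into probe sets. The deposited intensities were on a linear scale, with array medians from 32.5 to 34.2, and hold no detection calls, so fold changes of genes near the lowest values depend on the background estimate made by the authors. All further steps were done here. The log2 of each deposited intensity was taken. Probe sets were tested if they lay above the 40th percentile of all values (an intensity of 14.9, or 3.90 on the log2 scale) on at least 2 arrays, and the 68 control probe sets of the array were left out, which kept 13895 probe sets for 8198 genes.

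Gene symbols came from the platform's annotation, and probe sets with several symbols (1043) or with none (2169) were tested but given no gene name. Of 19071 probe sets with a single symbol, 19059 were found by gene identifier in the RefSeq table of GRCh38.p14, which was used only for names and changed 0 symbols. Genes that the array reads only through probe sets shared between genes therefore have no value of their own.

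A linear model with one mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes without trend and not robust). The contrasts drawn from it were E2 against vehicle within each virus group, AdERb moi 5 against Ad and AdERb moi 50 against Ad with vehicle, AdERb moi 50 against AdERb moi 5 with vehicle, AdERb moi 50 against Ad with E2, and the difference of the E2 response between AdERb at either moi and Ad. Tests were two-sided, with Benjamini-Hochberg adjustment over the probe sets within a contrast, and a change was called at an adjusted p under 0.05. The fit had 6 residual degrees of freedom and 3.59 prior degrees of freedom, and the typical standard error (SE) of a log2 fold change between 2 groups was 0.124. The number of arrays limits the precision. With 2 arrays against 2, the smallest p of an exact permutation test of a single gene is 0.333, so gene calls rest on the spread that limma shares across probe sets.

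One probe set stood for each gene, the tested one with the highest mean over the arrays. The genes named were set by a rule. For E2 in Ad-infected cells, E2 in AdERb moi 50 cells, and AdERb moi 50 against Ad with vehicle, it takes the 8 largest rises and the 8 largest falls among called genes for which both arrays of one group lay above both of the other. For the other contrasts between 2 groups it takes 4 of each. For the differences of E2 responses it takes 5 of each, without the condition on single arrays. ESR1, ESR2, PGR, TFF1, GREB1, CCND1, MYC, CXCL12 and CDKN1A were given in every comparison, and up to 4 called members with the smallest p could be named for each gene list. The contrasts, filter, threshold, naming rule and 25 gene lists were chosen before the data were examined. The lists covered classical E2-induced and E2-repressed genes, estrogen receptors and coregulators, S phase, mitosis, growth arrest, TGF-beta signalling, growth factors, apoptosis (2 lists), p53 targets, interferon, NF-kB, immediate early genes, unfolded protein response, heat shock proteins, cholesterol synthesis, ribosome biogenesis, glycolysis and hypoxia, xenobiotic and oxidative stress genes, epithelial junctions, and luminal, basal, fibroblast, and leukocyte and endothelial markers. Lists were written from general knowledge and some genes are on more than 1 of them. Each list was tested against all other genes with limma's camera at a preset correlation of 0.01, with adjustment over the lists within a contrast. A list count adjusted over the list alone comes from the members' p-values with Benjamini-Hochberg adjustment within that list.

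The gene and list tests were tried on simulated data for E2 in Ad-infected cells only. For the gene test 200 of 13895 probe sets were changed in each of 10 draws. The gene test called 93.4% of 2-fold and 99.8% of 4-fold changes, all with the right sign, and 6.12% of its calls were false. A list shifted by 0.3 was called in 10 of 10 draws. Noise was drawn independently for each probe set, so the draws cannot show how the list test behaves when genes vary together. Correlations of fold changes between contrasts were set beside those of 100 simulated sets of unchanged arrays.

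Alternatives tried were no filter, a stricter filter at the 60th percentile, quantile normalization of the deposited values again, centring each array on its median, an added offset of 32 before the log2, eBayes with trend and robust, a fit to only the groups compared, a replicate block, a requirement of at least a 2-fold change, and leaving out each array in turn. For lists they were an estimated correlation per list, fry, the mean over a gene's probe sets, and several of the settings above. Quantile normalization for the list tests was added after seeing the data. No array was left out of the main comparisons.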

Results

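Gene expression was read on 12 arrays of MCF-7 cells, a breast cancer line with estrogen receptor alpha (ESR1) of its own. The cells carried an adenovirus with estrogen receptor beta (ESR2) as insert, at a multiplicity of infection of 5 (AdERb5) or 50 (AdERb50), or a virus without insert at 50 (Ad), and received vehicle or 10 nM estradiol (E2) for 24 h. Each of the 6 groups had 2 arrays, and 13895 probe sets for 8198 genes were tested. Fold changes are log2 values with the standard error (SE) of the linear model, and n = 2 arrays per group throughout. The adjusted p-values measure only the spread between these samples, because the labels do not say whether the replicates were separate cultures. Across all probe sets, which are not independent replicates, replicate arrays correlated with r of 0.993 to 0.996 and arrays of different groups with r of 0.930 to 0.993. The first principal component held 54.7% of the variance and the second 19.2%.

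ESR2 was high only in cells that carried its virus. Its probe set with the highest mean had a mean log2 intensity of 4.01 (SD 0.02) in Ad vehicle cells, 13.11 (SD 0.32) in AdERb5 and 14.62 (SD 0.04) in AdERb50. ESR2 thus rose by 9.09 ± 0.14 (SE; adjusted p = 5.8e-10) at the lower and by 10.60 ± 0.14 (adjusted p = 1.3e-10) at the higher virus dose. These folds are not exact at either end. In Ad vehicle cells the intensity was near the filter level (16.2 against 14.9), and with an offset of 32 added the rises were 7.52 and 9.03. In AdERb50 vehicle cells the probe set was the brightest of all on both arrays, where the signal may be saturated. The other 2 tested ESR2 probe sets were higher by 10.02 and 10.11 in AdERb50, while the 2 left lay below the filter and differed by only 0.06 and 0.15. A probe set outside the inserted part checks nothing. E2 gave no call for ESR2 in any virus group (adjusted p = 0.966, 0.989 and 0.207 in Ad, AdERb5 and AdERb50). In AdERb50 cells, though, all 3 tested probe sets were lower with E2 (−0.26, −0.32 and −0.18, none called), measured from a level at the top of the range. The cells' own receptor moved the other way. ESR1 fell by 1.22 ± 0.09 (adjusted p = 2.0e-05) in AdERb50 against Ad, with all 6 of its other tested probe sets called lower, and it was not called in AdERb5 (−0.03, adjusted p = 0.991), where its 6 other probe sets were lower without a call (−0.93 to −0.35, adjusted p = 0.0946 to 0.831).

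The first question was what E2 does in cells without the ESR2 virus, that is, in Ad-infected cells. The estrogen-responsive growth regulator GREB1 rose by 5.93 ± 0.16 (adjusted p = 2.9e-08), the gap junction gene GJA1 by 5.54 ± 0.18, CCN5 by 5.40 ± 0.08, OLFML3 by 4.97 ± 0.27 and EPB41L3 by 4.84 ± 0.27. PEG10, the cytokine receptor gene IL17RB and the progesterone receptor PGR rose by 4.76 ± 0.15, 4.71 ± 0.17 and 4.70 ± 0.28. CLC fell by 5.24 ± 0.25, the cytokine receptor IL1R1 by 4.56 ± 0.16, the matrix gene FBN2 by 3.98 ± 0.34, and CCR1 (−3.66 ± 0.22) and HOPX (−3.44 ± 0.24) also fell. CALD1, HCAR3 and TGFB2 fell by 3.20 ± 0.37, 3.18 ± 0.21 and 2.99 ± 0.25. By its other probe sets, all called, CALD1 was at −1.83, −1.59 and −1.20. TFF1 rose by 2.12, MYC by 2.33, CXCL12 by 1.41 and the G1 cyclin CCND1 by 1.11, ESR1 fell by 0.59, and the CDK inhibitor CDKN1A was not called (−0.15, adjusted p = 0.207).

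Of 44 classical E2-induced genes, 37 rose and 1 fell (median 1.78, adjusted p = 7.9e-31; 0.00025 with an estimated correlation), RAB31 and CTSD by 3.88 and 2.33 among them. Of 23 classical E2-repressed genes, 16 fell and 1 rose (median −0.76, adjusted p = 8.0e-08; 0.0243 with an estimated correlation), with BIK at −2.09, EPAS1 at −2.01 and ERBB2 at −1.17. Mitosis genes rose as a group (15 of 28 up and 0 down, 20 when adjusted over the list alone; median 0.65, adjusted p = 1.0e-10, and 0.00327 with an estimated correlation), led by CDK1 at 2.0, PRC1 at 1.74 and UBE2C at 1.21. S phase genes did so too (15 of 42 up and 2 down, 18 and 3 over the list alone; median 0.31, adjusted p = 4.0e-05, and 0.0153 with an estimated correlation), with RRM2 at 2.90 and MCM3 at 0.93. Ribosome biogenesis genes rose in 21 of 30 cases (median 0.56), NF-kB genes rose in 11 of 23 and fell in 1 (median 0.38), and TGF-beta genes fell in 16 of 34 and rose in 2 (median −0.28), with FST up by 2.42 and BMP4 at −1.57. Each of these 3 lists lost its call with an estimated correlation (adjusted p = 0.0695). CXCL8 and CCL2, which attract leukocytes, rose by 2.86 and 2.10.

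E2 changed 3557 probe sets in Ad cells, 1465 up and 2092 down. The excess of falls depended on scaling, since quantile normalization gave 1698 up and 1763 down, and median centring 1643 and 1784. Of the 3557, 806 passed when a change of at least 2-fold was required. Without replicate 1 or 2 of the Ad E2 arrays the count was 2349 or 2262. For 9 of the 16 genes named by size the lower group lay below the filter level, where the fold depends on the background estimate. With an offset of 32 added all 16 were still called. The log2 value of the change became over 1.5 times smaller for GJA1 (3.13), OLFML3 (2.95), EPB41L3 (3.11), CLC (−3.17), FBN2 (−2.30), CCR1 (−1.71), HOPX (−1.73), CALD1 (−1.84) and HCAR3 (−1.36). The others shrank less on the log2 scale, GREB1 to 4.42 and CCN5 to 3.79 among them. The 3' minus 5' signal of the ACTB control, a measure of RNA integrity, was higher by 0.16 in E2 than in vehicle arrays within virus groups (exact stratified permutation p = 0.00926, two-sided, the smallest that 216 arrangements allow), so it moved together with every gene group that followed E2. For GAPDH the difference was 0.04 (exact stratified permutation p = 0.278).

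**Figure D1:**
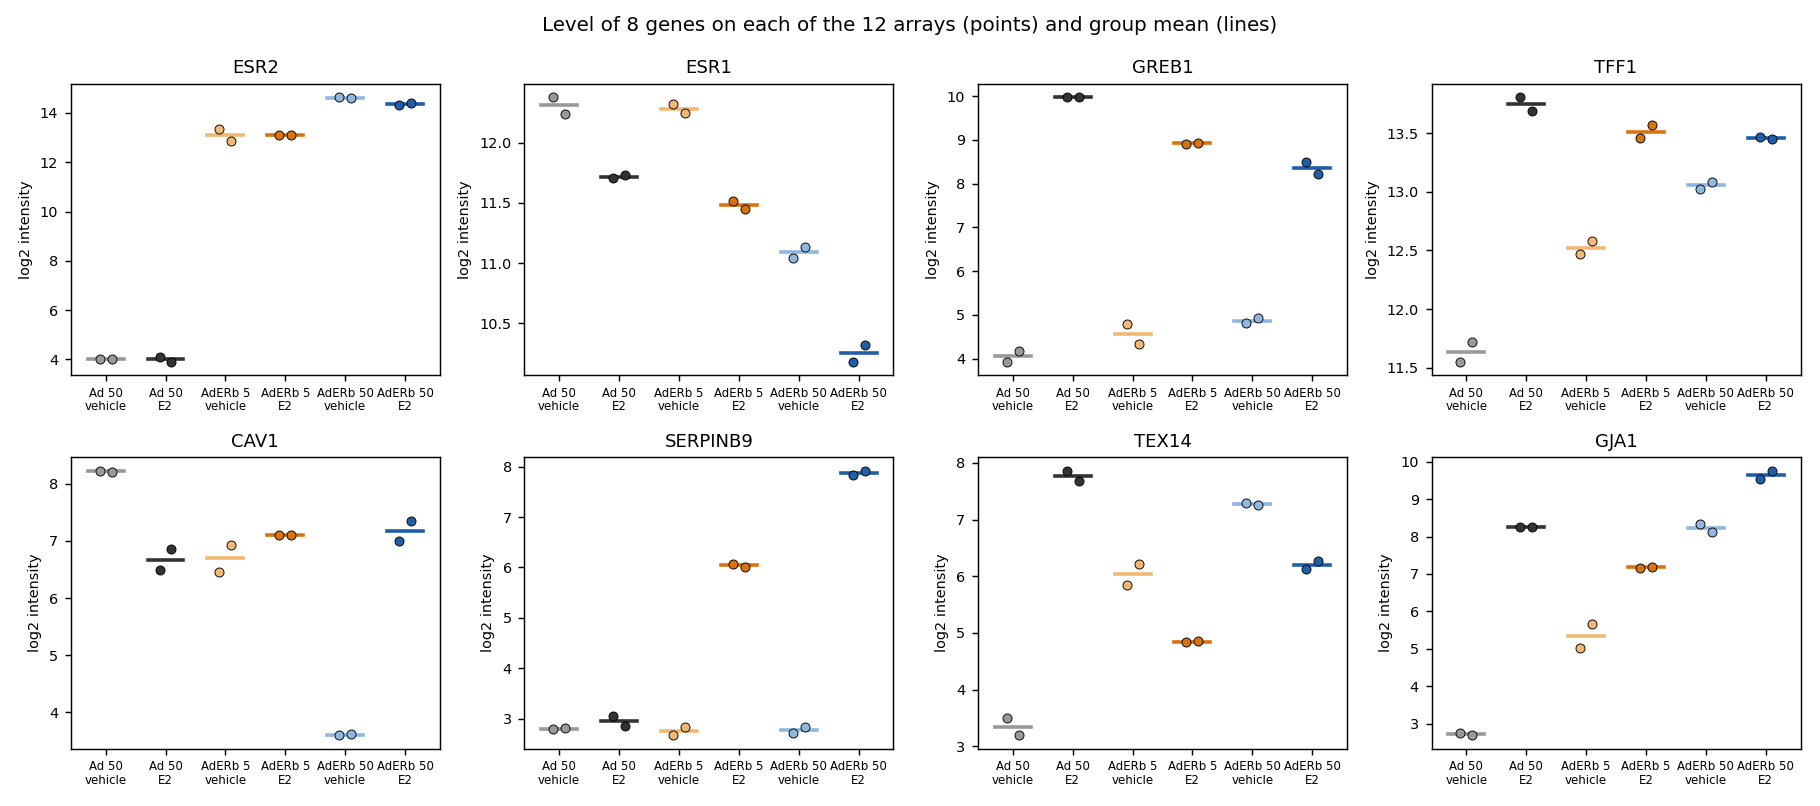
Log2 intensity of CAV1, ESR1, ESR2, GJA1, GREB1, SERPINB9, TEX14 and TFF1 in the 6 groups, with points for arrays and lines for group means. ESR2 was 10.60 higher in AdERb50 than in Ad vehicle cells, and GREB1 rose by 5.93 with E2 in Ad cells and by 3.50 in AdERb50 cells.

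The second question was how cells with the smaller amount of ESR2 virus answer to E2. In AdERb5 cells IL17RB rose by 6.02 ± 0.17, the AP-1 subunit FOS by 4.91 ± 0.11, GREB1 by 4.35 ± 0.16 (adjusted p = 2.5e-07) and GPRC5A by 4.06 ± 0.11. IL1R1 fell by 4.65 ± 0.16, CLC by 4.23 ± 0.25, FBN2 by 3.60 ± 0.34 and CALD1 by 3.32 ± 0.37. By its other probe sets CALD1 was at −1.18, −1.23 and −0.74, the last not called (adjusted p = 0.0563). PGR rose by 3.26, MYC by 2.19 and TFF1 by 0.99, and ESR1 fell by 0.80. CXCL12 and CCND1 rose by 0.51 and 0.47 (adjusted p = 0.0123 and 0.033). The CXCL12 call was lost without AdERb5 vehicle replicate 1 (0.0887) or AdERb5 E2 replicate 2 (0.072), and that of CCND1 without any single AdERb5 array (0.0802 to 0.153) or without the filter (0.0534). By its second probe set CXCL12 rose by 0.58 (adjusted p = 0.00194). CDKN1A was not called (−0.20, adjusted p = 0.115).

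Mitosis genes rose in 23 of 28 cases and fell in 0, or 24 and 1 over the list alone (median 1.40, adjusted p = 1.0e-14; 0.00124 with an estimated correlation), with PRC1 at 2.04, UBE2C at 1.83 and NUSAP1 at 1.68. Of 42 S phase genes, 20 rose, or 22 over the list alone (median 0.46, adjusted p = 2.5e-08; 0.00355 with an estimated correlation), RRM2 by 3.43 and TK1 by 1.01. Classical E2-induced genes rose in 33 of 44 cases and fell in 2 (median 0.84, adjusted p = 8.3e-17; 0.00124 with an estimated correlation), and the E2-repressed genes fell in 16 of 23 and rose in 2 (median −0.76, adjusted p = 7.5e-08; 0.0199 with an estimated correlation), LIMA1 and ERBB2 each at −1.53. NF-kB genes rose in 14 of 23 cases and fell in 1, or in 17 and 2 over the list alone (median 0.88, adjusted p = 9.9e-09; 0.0199 with an estimated correlation), with the chemokine genes CXCL8, CXCL2 and CXCL1 up by 3.55, 3.25 and 3.20 and the NF-kB inhibitor TNFAIP3 by 2.04. Ribosome biogenesis (17 of 30 up, 1 down), unfolded protein response (12 of 35 up, 1 down), interferon (13 of 32 up, 7 down), immediate early (14 of 32 up, 7 down) and heat shock genes (5 of 21 up) shifted upward and TGF-beta genes downward (10 of 34 down, 1 up). These calls were lost with an estimated correlation (adjusted p = 0.133, 0.343, 0.217, 0.0593, 0.184 and 0.0666).

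The AdERb5 response held 3259 probe sets, 1484 up and 1775 down, 739 of them at the 2-fold requirement and 2122 without AdERb5 E2 replicate 2. The offset made the log2 value of 5 changes over 1.5 times smaller, FOS at 2.97, IL1R1 at −2.93, CLC at −2.75, FBN2 at −2.11 and CALD1 at −1.49, all still called. GREB1 went to 3.21.

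The third question was the E2 response under the larger amount of ESR2 virus. In AdERb50 cells IL17RB rose by 6.42 ± 0.17, the protease inhibitor SERPINB9 by 5.10 ± 0.10 (adjusted p = 7.9e-09), complement C3 by 4.96 ± 0.20, FOS by 4.62 ± 0.11 and the steroid dehydrogenase HSD11B2 by 4.36 ± 0.10. PTPRH, OLFML3 and CHST1 rose by 3.97 ± 0.13, 3.89 ± 0.27 and 3.8 ± 0.17. TMEM259 fell by 3.88 ± 0.42, RAB3D by 2.88 ± 0.17, TMEM45A by 2.87 ± 0.11, CLC by 2.77 ± 0.25 and the thyroid hormone deiodinase DIO3 by 2.61 ± 0.43. ASB9, EIF2S3 and CALD1 fell by 2.28 ± 0.16, 2.20 ± 0.45 and 2.12 ± 0.37. The other 3 CALD1 probe sets were not called, and of the other 2 for TMEM259, 1 fell by 2.71 and 1 was not called (−0.62, adjusted p = 0.164). GREB1 rose by 3.50, PGR by 2.71, MYC by 1.68 and CCND1 by 0.85, and ESR1 fell by 0.84. TFF1 rose by 0.40 (adjusted p = 0.011), a call lost in a fit to only the groups compared (0.06) and without AdERb50 vehicle replicate 1 (0.0548). CDKN1A fell by 0.31 (adjusted p = 0.019) but not in a fit to only the groups compared (0.112) or without any one AdERb50 array (0.0506 to 0.0713), and CXCL12 was not called (−0.14, adjusted p = 0.46).

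Classical E2-induced genes rose in 32 of 44 cases and fell in 3, or 35 and 3 over the list alone (median 0.85, adjusted p = 7.7e-15; 0.00215 with an estimated correlation), the cyclin CCNA1 by 3.75 and PRSS23 by 2.26. Immediate early genes (17 of 32 up, 5 down; KLF4 at 1.74, ZFP36 at 0.92), glycolysis and hypoxia genes (13 of 35 up, 2 down; PFKFB3 at 2.22, CA12 at 1.89) and E2-repressed genes (11 of 23 down, 2 up; IL1R1 at −1.98) were called with adjusted p = 0.0016, 0.00462 and 0.00919. None of these 3 calls held with an estimated correlation (0.0581, 0.241 and 0.241). Mitosis genes rose in 8 of 28 cases and fell in 0 (median 0.14), TACC3 by 2.79 and PRC1 by 1.72, and S phase genes rose in 10 of 42 and fell in 5 (median 0.15), but neither list was called (adjusted p = 0.0881 and 0.215). NF-kB genes rose in 9 of 23 cases and fell in 1, without a call for the list (adjusted p = 0.0543). The response held 3582 probe sets, 1895 up and 1687 down (1844 and 1872 under quantile normalization, 2064 and 1476 after median centring), with 901 at the 2-fold requirement and 2123 in a fit to only the groups compared. For 8 of the 16 genes named by size the lower group lay below the filter level. With the offset all 16 were still called, with log2 values over 1.5 times smaller for 11 genes: SERPINB9 was 2.78, FOS 3.02, HSD11B2 1.78, PTPRH 2.32, OLFML3 2.16, TMEM259 −2.14, RAB3D −1.34, TMEM45A −1.69, CLC −1.54, ASB9 −1.52 and CALD1 −0.82. C3 and CHST1 went to 3.89 and 3.03.

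Across probe sets the E2 responses of Ad and AdERb5 cells correlated with r = 0.817, those of AdERb5 and AdERb50 cells with r = 0.673, and those of Ad and AdERb50 cells with r = 0.470, without shared arrays. Of the 1465 probe sets up in Ad cells, 955 were also up in AdERb5 cells (156 expected from independent lists) and 683 in AdERb50 cells (200 expected). Of the 2092 down in Ad cells, 1314 were also down in AdERb5 (267 expected) and 820 in AdERb50 (254 expected). Calls in opposite directions numbered 18 for AdERb5 and 191 for AdERb50.

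The next question was what ESR2 does without added ligand. In AdERb5 against Ad vehicle cells, after ESR2 itself, EPB41L3 rose by 3.28 ± 0.27, CCN5 by 2.75 ± 0.08 (adjusted p = 1.6e-07) and TEX14 by 2.69 ± 0.14. The cholesterol exporter ABCA1 (second probe set −0.91, adjusted p = 0.245) and FOXI1 both fell by 1.54 ± 0.12, the caveolar coat gene CAV1 by 1.53 ± 0.17 and the vasoconstrictor EDN1 by 1.39 ± 0.25 (adjusted p = 0.0376). TFF1 rose by 0.89 (adjusted p = 0.00156) and MYC by 0.73 (adjusted p = 0.00673), while PGR, GREB1, CCND1, CXCL12 and CDKN1A were not called (0.25, 0.52, 0.38, 0.18 and −0.04; adjusted p = 0.9, 0.235, 0.374, 0.746 and 0.973). Classical E2-induced genes rose in 11 of 44 cases and fell in 1, or 19 and 1 over the list alone (median 0.27, adjusted p = 4.7e-22; 0.00068 with an estimated correlation), with CTSD at 1.72, RAB31 at 1.58 and IGFBP4 at 1.06. Of 42 S phase genes 0 were called, 5 up over the list alone (median 0.12, adjusted p = 0.00082), and of 28 mitosis genes 1 was, 2 over the list alone (median 0.10, adjusted p = 0.001); both lists kept the call with an estimated correlation (0.0446). The ribosome, E2-repressed and glycolysis lists were called with 0 members called, at medians of 0.12, −0.12 and 0.07, and lost the call with an estimated correlation (adjusted p = 0.347 each). The E2-repressed list lost it also without Ad vehicle replicate 1 (0.112) or AdERb5 vehicle replicate 2 (0.0614) and the glycolysis list without any one Ad vehicle, AdERb5 vehicle or AdERb50 E2 array (0.0614 to 0.0945). The interferon genes OAS1 and IRF7 fell by 0.93 and 0.73, while the mean over all 32 interferon genes tested was −0.07.

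The comparison held 116 probe sets, 72 up and 44 down, and 55 at the 2-fold requirement. A fit to only the groups compared gave 23, and there EPB41L3 (0.0683), FOXI1 (0.0529), CAV1 (0.0733), EDN1 (0.0683), TFF1 (0.0865), MYC (0.129), IGFBP4 (0.0695), OAS1 (0.128) and IRF7 (0.098) were not called. Without Ad vehicle replicate 1, Ad vehicle replicate 2 or AdERb5 vehicle replicate 1 the count was 72, 73 or 60. MYC lost its call without the first or the last of these (0.0615 and 0.0535). EDN1 did so without any one Ad or AdERb5 array (0.0628 to 0.301), without the filter (0.102) and under quantile normalization (0.0711). With the offset EPB41L3 was 1.76, CCN5 1.48, TEX14 1.21, ABCA1 −0.65, FOXI1 −0.65 and EDN1 −0.88. These groups differ in total virus dose as well as in ESR2.

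At equal virus dose, AdERb50 against Ad vehicle cells, the effect was far larger. EPB41L3 rose by 5.58 ± 0.27, GJA1 by 5.51 ± 0.18, the dehydrogenase DHRS2 by 4.65 ± 0.15, CCN5 by 4.51 ± 0.08 (adjusted p = 1.4e-09), DIO3 by 4.25 ± 0.43, TEX14 by 3.93 ± 0.14 and the small heat shock protein CRYAB by 3.67 ± 0.11. CAV1 fell by 4.62 ± 0.17 (adjusted p = 2.2e-07), FBN2 by 3.86 ± 0.34, HCAR3 by 3.55 ± 0.21, HOPX by 3.27 ± 0.24 and TGFB2 by 3.05 ± 0.25. CCR1, IL1R1 and FMO5 fell by 2.89 ± 0.22, 2.77 ± 0.16 and 2.72 ± 0.14. TFF1 rose by 1.43, MYC by 1.23 and GREB1 by 0.81 (adjusted p = 0.00382), while CCND1 (0.35, adjusted p = 0.0817), CDKN1A (0.23, adjusted p = 0.0562) and CXCL12 (−0.10, adjusted p = 0.545) were not called. PGR rose by 0.88 (adjusted p = 0.0398), a call that was lost without the filter (0.0737), under quantile normalization (0.0609), with the offset (0.082), in a fit to only the groups compared (0.127) and without any one Ad array, either AdERb50 E2 array or AdERb50 vehicle replicate 1 (0.0516 to 0.226).

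S phase genes rose in 25 of 42 cases and fell in 1 (median 0.51, adjusted p = 1.9e-11; 0.00357 with an estimated correlation), with thymidylate synthase TYMS at 2.21, PCNA at 1.27 and FEN1 at 1.22, and DUT at −1.40. Classical E2-induced genes rose in 23 of 44 and fell in 6 (median 0.43, adjusted p = 8.1e-08; 0.00716 with an estimated correlation), CTSD by 2.77, RAB31 by 2.76 and FHL2 by 1.99. Mitosis genes rose in 10 of 28 and fell in 2, or 13 and 2 over the list alone (median 0.31, adjusted p = 0.00052; 0.0413 with an estimated correlation), PTTG1 by 2.08. Cholesterol and fatty acid synthesis genes fell in 16 of 28 cases and rose in 1 (median −0.39, adjusted p = 9.2e-05), INSIG2 at −1.78, MVD at −1.07 and SREBF1 at −0.94, but not with an estimated correlation (adjusted p = 0.211). E2-repressed genes fell in 15 of 23 (CRABP2 at −1.70, ERBB2 at −1.08), TGF-beta genes in 17 of 34 with 4 up (THBS1 at −1.77) and epithelial junction genes in 13 of 31 with 1 up (CLDN1 at −1.94). Ribosome genes rose in 15 of 30 with 1 down, heat shock genes in 6 of 21 with 1 down and p53 targets in 7 of 22 with 1 down (ZMAT3 by 1.11, FAS by 1.00). These calls were lost with an estimated correlation (adjusted p = 0.0899, 0.122, 0.249, 0.249, 0.137 and 0.165), and that of the junction genes also without Ad vehicle replicate 1 (0.0868).

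The comparison held 4146 probe sets, 1371 up and 2775 down, 768 at the 2-fold requirement and 2650 without Ad vehicle replicate 1. The share of calls that were up was 33.1% and became 49.9% under quantile normalization, which makes the arrays' distributions equal, but 34.6% after median centring. The excess of falls was thus lost under only 1 of these 2 scalings. For 10 of the 16 genes named by size the lower group lay below the filter level. With the offset all 16 were still called. The log2 value became over 1.5 times smaller for GJA1 (3.10), CCN5 (2.96), DIO3 (2.61), TEX14 (2.15) and CRYAB (2.32). Among the falls it did so for CAV1 (−2.91), FBN2 (−2.28), HCAR3 (−1.43), HOPX (−1.68) and CCR1 (−1.53). The others, EPB41L3 and TGFB2 among them, shrank less on the log2 scale.

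This effect without added ligand resembled that of E2. Across probe sets it correlated with the E2 response of Ad cells at r = 0.601, where the shared Ad vehicle arrays alone gave 0.499 in simulation, and the covariance was 0.176 against 0.0139 simulated. Correlations without shared arrays were 0.482 for AdERb50 against Ad vehicle with the E2 response of AdERb5 cells, and 0.459 for AdERb50 against AdERb5 vehicle with the E2 response of Ad cells. GJA1, CCN5, EPB41L3, FBN2, CCR1, HOPX, HCAR3, TGFB2 and IL1R1 were named by size in both E2 against vehicle in Ad cells and AdERb50 against Ad vehicle cells, and each moved the same way in both. Of 1465 probe sets up with E2 in Ad cells, 557 were up in AdERb50 vehicle cells (145 expected), and of 2092 down, 1336 were down (418 expected), while 149 were called in opposite directions. Part of these overlaps may come from the shared vehicle arrays.

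**Figure D2:**
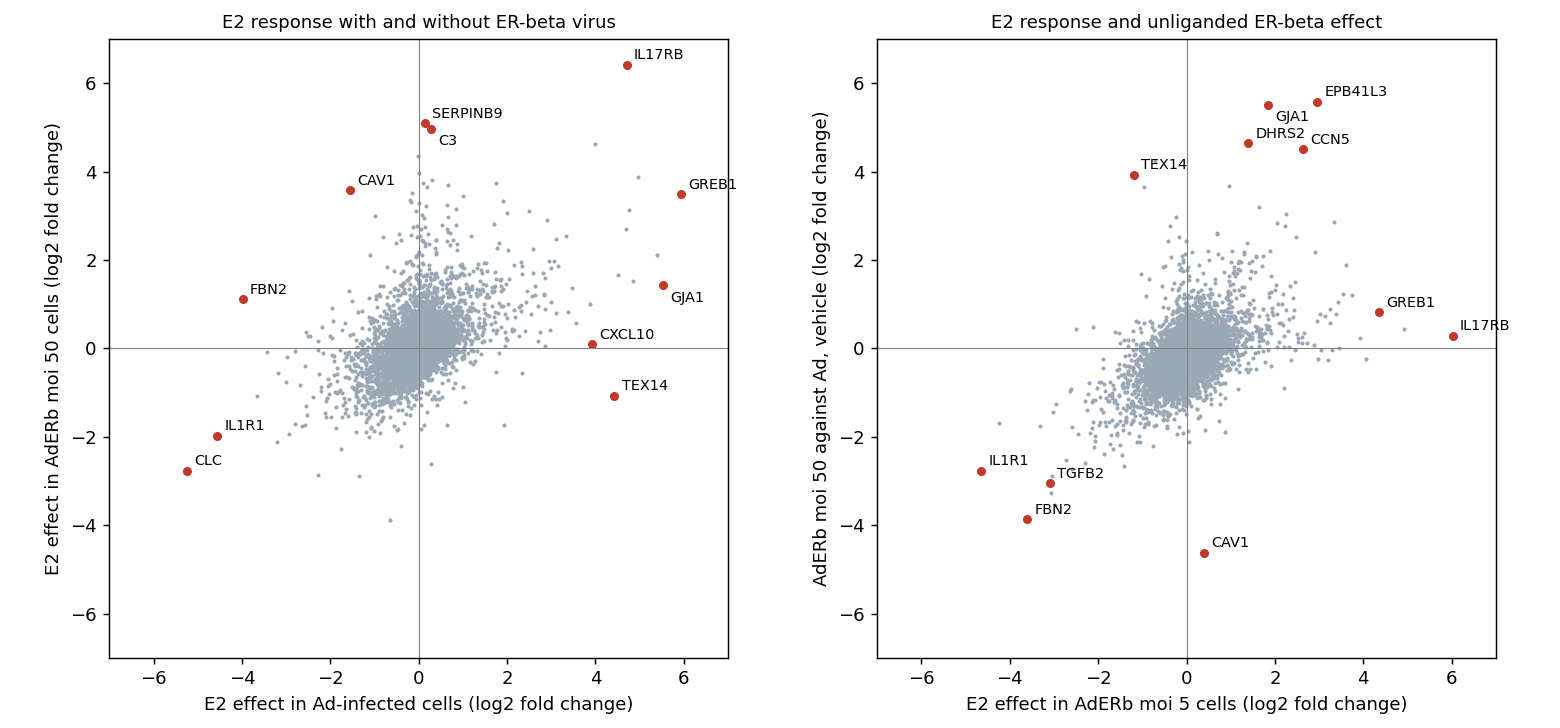
Log2 fold changes of the probe set that stood for each gene, without ESR2. The left panel sets E2 responses with and without the ESR2 virus against each other. The right panel sets AdERb50 against Ad vehicle (vertical) against the E2 response of AdERb5 cells (horizontal). The right pair shares no arrays and had r = 0.482 across all 13895 tested probe sets, more than the points drawn.

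AdERb50 against AdERb5 vehicle cells asked what the 10 times larger virus dose adds. ESR2 rose by 1.51 ± 0.14 (adjusted p = 0.000134), perhaps too little because its probe set was the brightest on the AdERb50 arrays. The other 2 tested ESR2 probe sets, less bright, rose by 1.92 and 1.54. DHRS2 rose by 3.09 ± 0.15, DIO3 by 3.0 ± 0.43, GJA1 by 2.88 ± 0.18 and EPB41L3 by 2.31 ± 0.27. FBN2 fell by 3.68 ± 0.34, HCAR3 by 3.18 ± 0.21, CAV1 by 3.10 ± 0.17 and HOPX by 2.68 ± 0.24. ESR1 fell by 1.19, TFF1 rose by 0.53 and MYC by 0.50, while PGR, GREB1, CCND1 and CXCL12 were not called (0.64, 0.29, −0.03 and −0.28; adjusted p = 0.14, 0.21, 0.894 and 0.127). The second CXCL12 probe set went the other way and was called (0.51, adjusted p = 0.00552). CDKN1A rose by 0.27 (adjusted p = 0.0411), but not after median centring (0.0639), in a fit to only the groups compared (0.144) or without any one AdERb5, Ad E2 or AdERb50 vehicle array (0.0618 to 0.131). S phase genes rose in 20 of 42 cases and fell in 1 (median 0.42, adjusted p = 1.3e-10; 0.00444 with an estimated correlation), TYMS by 1.82, MCM5 by 1.61 and PCNA by 1.12. Cholesterol synthesis genes fell in 14 of 28 (INSIG2 at −1.45), E2-repressed genes fell in 14 of 23 with 2 up (IL1R1 at −2.13, CRABP2 at −1.52), p53 targets rose in 9 of 22 (FAS by 1.28, TRIAP1 by 0.91), and E2-induced genes rose in 13 of 44 and fell in 6 (FHL2 by 1.34). These 4 lists lost the call with an estimated correlation (adjusted p = 0.16, 0.102, 0.102 and 0.102), and the E2-induced list also without the filter (0.0764). Mitosis genes rose in 3 of 28 and fell in 2 (median 0.18, adjusted p = 0.0139), a call lost with an estimated correlation (0.102) and under quantile normalization (0.103). The comparison held 2866 probe sets, 959 up and 1907 down, with 447 at the 2-fold requirement, 1475 in a fit to only the groups compared and 1654 without AdERb5 vehicle replicate 2. The share of calls that were up was 33.5% and became 48.2% under quantile normalization but 28.1% after median centring. With the offset FBN2 was −2.14, HCAR3 −1.18, CAV1 −1.63 and HOPX −1.26. ESR2 and virus dose rose together here.

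With E2 present, AdERb50 was compared with Ad at equal virus dose. The cystatins CST1 and CST4 rose by 5.64 ± 0.16 and 5.19 ± 0.14, the deubiquitinase OTUB2 by 5.36 ± 0.13 and ESR2 by 10.36 ± 0.14 (adjusted p = 1.7e-10; 8.78 with the offset). TMEM259 fell by 3.83 ± 0.42 (−2.35 and −0.51 by its other probe sets, the last not called, adjusted p = 0.23), the sulfate transporter SLC26A2 by 3.34 ± 0.36, SLC6A14 by 2.58 ± 0.14 and TRAF5 by 2.45 ± 0.14. CXCL12 fell by 1.65, GREB1 by 1.62 and ESR1 by 1.47, and MYC rose by 0.58. PGR and TFF1 fell by 1.11 and 0.29 (adjusted p = 0.014 and 0.0434). The call of PGR was lost without Ad E2 replicate 1 (0.0547), Ad E2 replicate 2 (0.0709) or AdERb50 E2 replicate 1 (0.0692), and that of TFF1 without any one AdERb50 array, Ad E2 array or AdERb5 E2 array (0.051 to 0.234), after median centring (0.0506), under quantile normalization (0.0704) or in a fit to only the groups compared (0.0887). CCND1 and CDKN1A were not called (0.09 and 0.08; adjusted p = 0.692 and 0.528). S phase genes rose in 21 of 42 cases and fell in 2 (median 0.36, adjusted p = 4.5e-06; 0.0203 with an estimated correlation), MCM5 by 2.05, CHEK1 by 1.61 and GINS2 by 1.53. Xenobiotic and oxidative stress genes rose in 11 of 26 and fell in 1, with the metallothioneins MT1X, MT2A and MT1F up by 2.95, 2.52 and 2.28. Immediate early genes rose in 14 of 32 and fell in 3, SPRY2 by 2.57. Basal markers rose in 6 of 11 and fell in 1, MYLK by 2.10, and cholesterol synthesis genes fell in 17 of 28 and rose in 1, MVD at −1.51. These 4 lists lost the call with an estimated correlation (adjusted p = 0.36, 0.0768, 0.307 and 0.448). Of the classical E2-induced genes 14 rose and 19 fell, without a call for the list (median −0.14, adjusted p = 0.626). The comparison held 4329 probe sets, 1820 up and 2509 down, 991 at the 2-fold requirement and 2790 without Ad E2 replicate 1, and with the offset TMEM259 was −2.10 and TRAF5 −1.23.

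Whether the ESR2 virus altered the E2 response was tested directly as the difference of responses. For AdERb5 minus Ad, SERPINB9 responded more to E2 by 3.14 ± 0.14 (adjusted p = 7.1e-06), CHST1 by 2.82 ± 0.24, PTPRH by 2.64 ± 0.19, OTUB2 by 2.36 ± 0.18 and HSD11B2 by 2.34 ± 0.14. The difference was negative for TEX14 (−5.62 ± 0.20, adjusted p = 2.3e-06), GJA1 (−3.70 ± 0.25), CCN5 (−2.75 ± 0.12), the lysosomal protease CTSD (−2.70 ± 0.14) and PODXL (−2.40 ± 0.22). TEX14 rose by 4.43 with E2 in Ad cells and fell by 1.19 in AdERb5 cells, and CTSD rose by 2.33 and fell by 0.37 (adjusted p = 0.0207), so both changed direction. The rise was smaller for GREB1 (−1.58, adjusted p = 0.00633), TFF1 (−1.13, adjusted p = 0.00234) and CXCL12 (−0.90, adjusted p = 0.0337), but for CXCL12 not without the filter (0.059) or without any one Ad or AdERb5 array (0.0612 to 0.14). The second CXCL12 probe set was called the same way (−1.17, adjusted p = 0.00232). No difference was called for PGR (−1.44, adjusted p = 0.161), CCND1 (−0.64, adjusted p = 0.225), MYC (−0.14, adjusted p = 0.871), ESR1 (−0.20, adjusted p = 0.731), ESR2 (0.02, adjusted p = 0.999) or CDKN1A (−0.04, adjusted p = 0.978).

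Classical E2-induced genes had a negative difference in 15 of 44 cases and a positive one in 1, or 26 and 2 over the list alone (median −0.54, adjusted p = 7.6e-26; 0.00043 with an estimated correlation), RAB31 with −1.66, while CCNA1 gained 1.63. NF-kB genes had a positive difference in 4 of 23 cases and a negative one in 0, or 11 and 1 over the list alone (median 0.79, adjusted p = 3.0e-09; 0.0225 with an estimated correlation), CXCL1 by 1.67 and TNFAIP3 by 1.56. Mitosis genes had a positive difference in 2 of 28, 4 over the list alone (median 0.40, adjusted p = 0.000114; 0.0225 with an estimated correlation), and immediate early genes in 3 of 32, or 6 up and 1 down over the list alone (median 0.27, adjusted p = 0.00055; 0.026 with an estimated correlation). The metallothionein MT1F differed by 1.21 and SLC2A1 by −1.26. The S phase, unfolded protein response and xenobiotic lists shifted up (medians 0.22, 0.19 and 0.18) and the ribosome and glycolysis lists down (−0.18 and −0.11), with 0, 0, 3, 0 and 1 members called. These calls were lost with an estimated correlation (adjusted p = 0.0645, 0.435, 0.334, 0.475 and 0.223). Those of the xenobiotic and glycolysis lists were lost also without AdERb5 vehicle replicate 2 (0.0643) and without Ad E2 replicate 2 (0.072). The growth factor list was called down with 4 of 31 members down, IGFBP4 at −1.15, although its median was 0.00865 and its mean −0.14. It lost the call with an estimated correlation (adjusted p = 0.0959) and without AdERb5 E2 replicate 2 (0.0697). The comparison held 196 probe sets, 111 up and 85 down, and 138 at the 2-fold requirement. The count was 126, 129, 126, 128, 129 and 129 without Ad vehicle replicate 1 or 2, Ad E2 replicate 1 or 2, AdERb5 vehicle replicate 1 and AdERb5 E2 replicate 2. The offset gave SERPINB9 1.31, PTPRH 1.13, OTUB2 1.49, HSD11B2 0.58, TEX14 −3.26, GJA1 −1.85 and CCN5 −1.48, all still called.

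**Figure D3:**
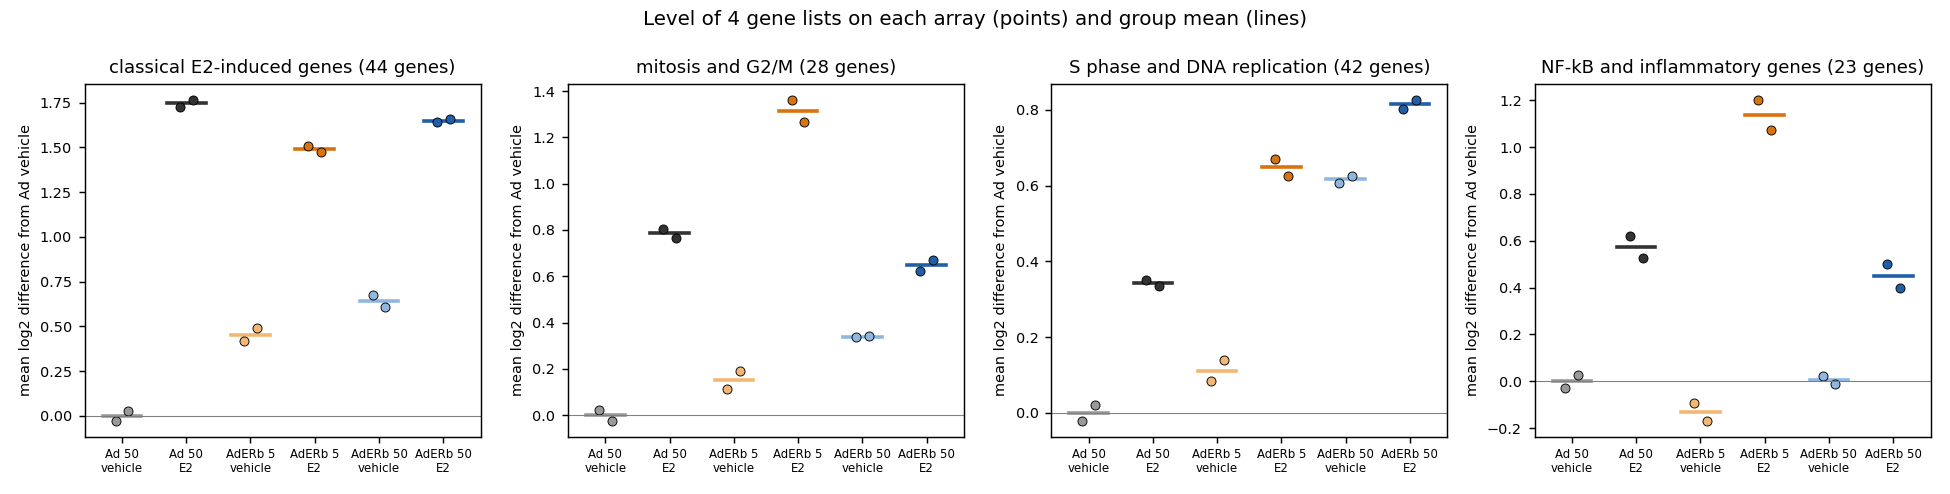
Mean level of the classical E2-induced, S phase, mitosis and NF-kB lists on each array relative to Ad vehicle (log2), by group, with points for arrays. Mitosis genes stood at 0.79 in Ad E2, 1.32 in AdERb5 E2 and 0.65 in AdERb50 E2 cells.

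For AdERb50 minus Ad, at equal virus dose, the difference was positive for CAV1 (5.13 ± 0.25), FBN2 (5.10 ± 0.48), SERPINB9 (4.95 ± 0.14, adjusted p = 2.9e-07), C3 (4.68 ± 0.29) and HSD11B2 (4.38 ± 0.14). CAV1 fell by 1.55 with E2 in Ad cells and rose by 3.58 in AdERb50 cells, and FBN2 fell by 3.98 and rose by 1.12 (adjusted p = 0.036), so both changed direction. Both rises started below the filter level of 3.90, from means of 3.60 for CAV1 and 3.68 for FBN2 in AdERb50 vehicle cells. There the fold depends on the background estimate. With vehicle, AdERb50 minus Ad was −4.62 for CAV1 and −3.86 for FBN2. Most of their positive differences thus lay in a lower level without ligand. The difference was negative for TEX14 (−5.50 ± 0.20), GJA1 (−4.11 ± 0.25), the interferon-induced chemokine CXCL10 (−3.82 ± 0.30), SLC26A2 (−3.67 ± 0.51) and EPB41L3 (−3.33 ± 0.39). TEX14 and SLC26A2 rose by 4.43 and 1.93 in Ad cells but fell by 1.07 and 1.74 in AdERb50 cells, whereas GJA1 and EPB41L3 rose in both. With vehicle, GJA1 stood at 2.75 and 2.68 on the Ad arrays and at 8.32 and 8.12 on the AdERb50 arrays. With E2 it stood at 8.26 and 8.25 against 9.54 and 9.76. The negative difference of GJA1 thus came with a higher level without ligand, not with a lower level with E2. GREB1 (−2.43), PGR (−1.99, adjusted p = 0.0095), TFF1 (−1.71), CXCL12 (−1.55) and MYC (−0.65, adjusted p = 0.0127; 0.0574 without Ad E2 replicate 1) had negative differences as well, while CCND1 (−0.26, adjusted p = 0.437), ESR1 (−0.24, adjusted p = 0.271), ESR2 (−0.24, adjusted p = 0.482) and CDKN1A (−0.15, adjusted p = 0.44) were not called. Classical E2-induced genes had a negative difference in 22 of 44 cases and a positive one in 5, or 27 and 5 over the list alone (median −0.68, adjusted p = 1.2e-10; 0.00552 with an estimated correlation), CTSD with −2.88 and RAB31 with −2.87, while CCNA1 gained 3.64. Mitosis genes had a negative difference in 5 of 28 and a positive one in 1 (median −0.46, adjusted p = 2.9e-05; 0.0244 with an estimated correlation), CDK1 with −1.82, and TACC3 with 1.95. Ribosome genes had a negative difference in 10 of 30 (MRTO4 at −1.12) and S phase genes in 5 of 42 with 1 positive (TYMS at −1.20). E2-repressed genes had a positive difference in 10 of 23 and a negative one in 1 (IL1R1 at 2.58, EPAS1 at 2.30). Xenobiotic genes had a positive one in 6 of 26, where MT1X and MT1F fell by 1.5 and 1.94 with E2 in Ad cells but rose by 1.08 and 0.62 in AdERb50 cells. These 4 lists lost the call with an estimated correlation (adjusted p = 0.18, 0.18, 0.18 and 0.34). The S phase list lost it also without the filter (0.124), under quantile normalization (0.0726) and without Ad vehicle replicate 1 (0.0646), AdERb50 E2 replicate 1 (0.106) or AdERb50 vehicle replicate 2 (0.0803), and the xenobiotic list without the last of these (0.0712). NF-kB genes were not called as a list (median 0.01, mean −0.13, adjusted p = 0.273), and CCL2 differed by −1.66.

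The AdERb50 difference held 1893 probe sets, 1272 up and 621 down, 806 at the 2-fold requirement and 1201 without Ad E2 replicate 1. The share of calls that were up was 67.2% and became 56.1% under quantile normalization and 66.0% after median centring. With the offset CAV1 was 3.31, FBN2 2.71, SERPINB9 2.75, HSD11B2 1.78, TEX14 −3.39, GJA1 −1.79 and EPB41L3 −1.64, all still called. Of 2757 genes with several tested probe sets, 0 had probe sets called in opposite directions for E2 in Ad cells, 2 in AdERb5 and 9 in AdERb50, and 18 for AdERb50 against Ad vehicle. CXCL12 had a second probe set that was higher by 0.67 there. Of the 6 other ESR1 probe sets, 4, 2 and 4 were called lower with E2 in Ad, AdERb5 and AdERb50 cells, and the other CCND1 probe set was not called with E2 in AdERb5 or AdERb50 cells. In the AdERb50 difference a single ESR1 probe set was called, at 0.91 (adjusted p = 0.0232).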

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

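Some tests here were chosen only after the result was seen. They were virus dose at moi 50 and a ceiling for mitosis genes, and every test of the resemblance between ESR2 virus and E2. The other tests here were chosen earlier, except that quantile normalization, part of both scaling tests, was added for lists after seeing the data. The results below stood out because the E2 response in cells with the ESR2 virus differed from that in Ad cells by a direct test of the difference (limma, adjusted p under the threshold; n = 2 arrays per group). All values are differences of log2 responses, AdERb minus Ad.

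At moi 5 the difference was called for 196 probe sets. Positive differences were largest among the named genes for SERPINB9 (3.14), CHST1 (2.82), PTPRH (2.64), OTUB2 (2.36) and HSD11B2 (2.34), and negative ones for TEX14 (−5.62), GJA1 (−3.70), CCN5 (−2.75), CTSD (−2.70) and PODXL (−2.40). TFF1 (−1.13), GREB1 (−1.58) and CXCL12 (−0.90) were called as well. List medians were −0.54 for classical E2-induced genes, 0.79 for NF-kB, 0.40 for mitosis, 0.27 for immediate early, 0.22 for S phase, 0.19 for unfolded protein response, 0.18 for xenobiotic, −0.18 for ribosome and −0.11 for glycolysis genes. The growth factor list was called down at a median of 0.00865, with 4 of 31 members down. With an estimated correlation the calls of S phase (adjusted p = 0.0645), unfolded protein response (0.435), xenobiotic (0.334), ribosome (0.475), glycolysis (0.223) and growth factor genes (0.0959) were lost.

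At moi 50 it was called for 1893 probe sets. The named genes were CAV1 (5.13), FBN2 (5.10), SERPINB9 (4.95), C3 (4.68) and HSD11B2 (4.38) on the positive side and TEX14 (−5.50), GJA1 (−4.11), CXCL10 (−3.82), SLC26A2 (−3.67) and EPB41L3 (−3.33) on the negative side. PGR (−1.99), TFF1 (−1.71), GREB1 (−2.43), MYC (−0.65) and CXCL12 (−1.55) were also called. List medians were −0.68 for classical E2-induced, 0.26 for E2-repressed, −0.15 for S phase, −0.46 for mitosis, −0.43 for ribosome and 0.17 for xenobiotic genes. With an estimated correlation the calls of E2-repressed, S phase and ribosome (adjusted p = 0.18 each) and xenobiotic genes (0.34) were lost.

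Mitosis genes responded more to E2 at moi 5 and less at moi 50 than in Ad cells. Virus dose alone is argued against for moi 50 by the design, which gave AdERb50 and Ad cells the same dose, so that it cannot enter their difference of −0.460; a ceiling is argued against because the genes stood 0.634 higher in AdERb5 than in AdERb50 cells with E2, and the scaling because both differences passed under 2 other scalings (largest adjusted p = 0.00058). For the moi 5 part (0.398) the insert and the smaller virus dose cannot be told apart, because no cells received the virus without insert at moi 5. Some of the moi 50 difference lay in the level without ligand. AdERb50 minus Ad cells had list medians of 0.311 with vehicle and −0.172 with E2. A raised level without ligand was not tested as a cause for this list. An effect of the amount of ESR2 may explain both parts, and it was not tested apart from virus dose.

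AdERb50 vehicle cells resembled E2-treated cells without added ligand. Shared control arrays are argued against as the whole cause by pairs of comparisons without common arrays (lower r = 0.459 across probe sets). Virus dose is argued against by the design, since E2 was compared within a dose and AdERb50 and Ad cells had the same moi per the labels. The r of 0.482 between E2 in AdERb5 cells and AdERb50 against Ad vehicle cells is no further test of dose. RNA integrity and ESR2 cannot be told apart here, because the AdERb50 vehicle arrays showed a share of 0.414 of the E2 shift in the ACTB 3' minus 5' signal with an SE of 0.248. This ACTB signal was alike in AdERb5 and AdERb50 vehicle arrays (0.627, SD 0.098, and 0.632), whose difference gave the r of 0.459 with E2 in Ad cells. That would go against RNA integrity, but the spread of the AdERb5 arrays leaves it open. The GAPDH signal was not alike, at 0.179 (SD 0.036) in AdERb5 and 0.235 (SD 0.018) in AdERb50 vehicle arrays. It was 0.126 (SD 0.072) in Ad vehicle and 0.178 (SD 0.072) in Ad E2 arrays. An effect of ESR2 without ligand may explain the resemblance, as could estrogen left in the medium, which was not tested.

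Classical E2-induced genes responded less to E2 at moi 50. A signal ceiling is argued against by the 19 of 44 members below the 90th percentile in every group (median −0.70), and the scaling by the largest adjusted p of 9.1e-10 under 2 other scalings. The list's median of −0.14 against Ad cells with E2 was near enough to 0 to meet the limit set earlier for a raised level without ligand. That limit did not consider single members, of which 14 were higher and 19 lower, so the median was not taken to decide. With vehicle, AdERb50 cells stood above Ad cells by a list median of 0.434. Relative to Ad vehicle, the list mean was 0.64 in AdERb50 vehicle cells, and with E2 1.75 in Ad and 1.65 in AdERb50 cells. For the list mean, most of the smaller response thus lay in the raised level without ligand. Single members differed. AdERb50 minus Ad was 1.43 with vehicle and −0.29 with E2 for TFF1, but 0.81 and −1.62 for GREB1. An effect of ESR2 stays open and was not tested apart from the fall in ESR1.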

How the results depend on the processing

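Quantile normalization of the list tests was the only alternative chosen after seeing the data. No direction reversed among the lists called in the main test, nor among single genes called in the main test or the alternative (0 reversed). Changes of sign in genes called in neither were not counted. Unless named here, the causes of the changes were not tested.

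A required change of at least 2-fold lowered the counts by construction, to 806, 739 and 901 for E2 in Ad, AdERb5 and AdERb50 cells, 55, 768 and 447 for AdERb5 against Ad, AdERb50 against Ad and AdERb50 against AdERb5 with vehicle, 991 for AdERb50 against Ad with E2, and 806 for the AdERb50 difference in E2 response. A fit to only the groups compared, with fewer arrays to estimate the spread, gave 2123 for E2 in AdERb50 cells, 23 for AdERb5 against Ad and 1475 for AdERb50 against AdERb5. Of 225 list tests 77 were called; 24 passed with an estimated correlation, all among the 77 with the same direction, and 131 with fry, 72 of them among the 77. Fry tests a list against no change and camera against all other genes, so their calls answer different questions. With fry 5 of the 77 lost the call, for AdERb5 against Ad the E2-repressed (0.0655), ribosome and glycolysis lists (0.13 each), and for the AdERb5 difference the ribosome (0.242) and unfolded protein response lists (0.104).

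With the replicate number as a replicate block, the counts were 3852, 3543 and 3912 for E2, 131, 4528, 3219 and 4692 for the virus comparisons in the order above, and 232 and 2103 for the differences. Residuals of same-numbered arrays correlated with r of 0.017 to 0.251 in 15 pairs of groups (median 0.137), over 0.1 in 10 of them, and the fifth principal component (3.0% of the variance) put replicate 1 below replicate 2 in all 6 groups. Arrays with the same number may thus share some variation, a hint from the data that the labels do not explain. The planned fit without the block was kept because not every pair was over 0.1, a limit that the plan did not set. All pairs had a positive r, and the block gave more calls in every comparison.

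Leaving out 1 array, with the lone array assumed to vary like the other groups, gave 2262 to 3663, 2122 to 3363 and 2711 to 3521 probe sets for E2; 60 to 126, 2650 to 4282, 1654 to 3035 and 2790 to 4416 for the virus comparisons; 126 to 196 and 1201 to 1787 for the differences; an ESR2 rise of 10.57 to 10.64; and 73 to 81 list calls. Counts moved by over 1.5 times without Ad vehicle replicate 1 (72 for AdERb5 and 2650 for AdERb50 against Ad, 126 for the AdERb5 difference) or 2 (73 and 129 for AdERb5), Ad E2 replicate 1 (2349 for E2 in Ad, 2790 for AdERb50 with E2, 126 and 1201 for the differences) or 2 (2262 and 128), AdERb5 vehicle replicate 1 (60 and 129) or 2 (1654), and AdERb5 E2 replicate 2 (2122 and 129).

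The share of calls that were up went from 41.2% to 49.1% (E2 in Ad), 52.9% to 49.6% (E2 in AdERb50), 33.1% to 49.9% (AdERb50 against Ad vehicle), 33.5% to 48.2% (AdERb50 against AdERb5) and 67.2% to 56.1% (AdERb50 difference) under quantile normalization, but in this order to 47.9%, 58.3%, 34.6%, 28.1% and 66.0% after median centring. Of 798 results for single genes, 767 were called and so had a call to lose. Of these 767, 55 lost it in a fit to only the groups compared, 17 without the filter and 11 with the offset. Under quantile normalization 8 lost it, after median centring 6, with the replicate block 3, and with trend and robust 0. More lost it when some single array was left out than under any of these settings.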

Other observations

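Several lists were not called for E2 in Ad cells, nor in AdERb50 cells where these are named below, yet held strong single responses in one or the other. In the list of estrogen receptors and coregulators (adjusted p = 0.744) NRIP1, an estrogen receptor corepressor, rose by 2.45 in Ad, 1.96 in AdERb5 and 1.31 in AdERb50 cells, a smaller response at moi 50 (−1.14, adjusted p = 0.00439), and CITED1 rose by 2.55 in AdERb50 cells (list adjusted p = 0.862 there). Among pro-apoptotic genes (adjusted p = 0.744) PMAIP1 rose by 1.95 and BAK1 fell by 1.32 in Ad cells, and among anti-apoptotic genes (adjusted p = 0.412) BCL2 rose by 0.81 with E2 in Ad and by 0.85 in AdERb50 cells, whereas it fell by 0.77 in AdERb50 against Ad vehicle cells. Among growth arrest genes (adjusted p = 0.398 in Ad and 0.862 in AdERb50 cells) FOXO1 rose by 2.45 with E2 in AdERb50 cells. Of fibroblast markers (adjusted p = 0.596 in Ad and 0.499 in AdERb50 cells) the collagen crosslinking gene LOX rose by 3.12 with E2 in AdERb50 cells, 3.19 more than in Ad cells (adjusted p = 1.1e-05), where it was not called (−0.07). The luminal regulators SPDEF, FOXA1 and GATA3 fell by 1.46, 0.76 and 0.71 in AdERb50 against Ad vehicle cells, where the luminal list was not called (adjusted p = 0.0625).

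In the cholesterol list (adjusted p = 0.438 for E2 in Ad cells) INSIG2 fell by 2.93, in the p53 list (0.596) ZMAT3 rose by 0.84, and in the growth factor list (0.509) FGF13 fell by 2.20 and IGFBP4 rose by 2.0. The immediate early list (0.318) was not called although FOS rose by 3.99, since 11 members rose and 10 fell. The xenobiotic (0.113), unfolded protein response (0.433), luminal (0.963) and leukocyte (0.382) lists were not called for E2 in Ad cells either, with MT1F down (−1.94) and TIPARP up (2.03) in the first. Heat shock (5 of 21 up), glycolysis (13 of 35 up, 4 down) and interferon genes (16 of 32 up, 7 down) were called up there, and basal (6 of 11 down, 1 up) and epithelial junction genes (11 of 31 down, 3 up) down, with FKBP4 at 1.35, CA12 at 2.16, CXCL10 at 3.93, MYLK at −2.50 and CLDN1 at −2.12. With an estimated correlation these 5 calls were lost (adjusted p = 0.127, 0.127, 0.184, 0.183 and 0.197), that of the basal genes also without the filter (0.0654) and that of the junction genes without Ad vehicle replicate 1 (0.0691). In AdERb50 against AdERb5 vehicle cells the heat shock (6 of 21 up, 1 down), interferon (9 of 32 up, 1 down) and ribosome lists (9 of 30 up, 1 down) were called up and the TGF-beta (13 of 34 down, 3 up), luminal (7 of 20 down, 2 up) and junction lists (10 of 31 down, 2 up) down, none of them with an estimated correlation (adjusted p = 0.16, 0.204, 0.286, 0.112, 0.259 and 0.248). There the ribosome call was lost also without the filter (0.0764) or without AdERb50 vehicle replicate 1 (0.062), the luminal call without AdERb5 vehicle replicate 1 (0.0711) or AdERb50 vehicle replicate 1 (0.0739), and the junction call under quantile normalization (0.0533), without AdERb5 vehicle replicate 2 (0.103) or without AdERb50 vehicle replicate 1 (0.0621). In AdERb50 against Ad vehicle cells the leukocyte list was called up (2 of 6 up, 4 not called; LAPTM5 at 0.76), but not with an estimated correlation (adjusted p = 0.249), without the filter (0.0555) or without AdERb50 vehicle replicate 2 (0.145).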
